A study of Mus musculus with 8 samples.

How the data were processed

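Chromatin immunoprecipitation with an antibody against FOS, followed by sequencing, was done on microglia sorted from the cortex of 4 mice at postnatal day 30, 4 h after IL-33 had been injected into a cerebral ventricle on 1 side. Each mouse gave a FOS library and an input library, so there were 4 FOS libraries and 4 inputs. All 4 mice had received IL-33, and no library of a vehicle-injected mouse was analysed here. The comparison of treated with untreated mice therefore could not be made from the libraries themselves.

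The values came as 1 table of regions. Per the file headers, the authors had merged 2 peak lists with the mergePeaks program of HOMER. The first was their merged list of FOS peaks. The second carried a column name that reads as the IL-33 side of a comparison of IL-33 with vehicle, and is called the IL-33 list here. The assay, libraries and thresholds behind the IL-33 list are not given in the sources used here. The submitters' processing notes name Bowtie2 and HOMER, without versions, and the builds mm10 and GRCm38. Peak caller settings and the use of the inputs are not given in the sources used here. The table had 10 columns and none with values per library, so sequencing depth per library is unknown and no value below has a replicate error. Intervals and tests describe this list of regions and cover counting error only, not differences between mice.

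The deposited score of each region is, per the file headers, a statistic that the authors' merge averaged over the peaks it joined. All 1300 regions of the IL-33 list alone had a score of 0, so the average in a region that held peaks of both lists was diluted. Multiplying by the number of merged peaks and dividing by the number of FOS peaks undid this. After it, 98.7% of the 1517 shared regions with 1 FOS peak and a restored score of 10 or more had a score that was a whole multiple of 0.1 once multiplied by the number of calls, with a tolerance of 0.02 of that step, against 45.9% as deposited and 97.6% in regions of the FOS list alone. The restored score was used unless the deposited score is named. The scale of the score is not given in the sources used here, so it served only to rank and compare regions within this list. Other deposited columns gave the number of merged peaks and their names. The number of merged peaks equalled the number of names in 32773 of 32773 regions. The name of a FOS peak ends in a number from 1 to 4, called its number of calls here. It was read as the number of FOS libraries that held the peak, an inference from its range, and calls could not be assigned to particular mice.

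Regions holding peaks of both lists were called shared, and the others FOS-only or IL-33-only. Genes came from an annotation table of the same build with start and end of each gene but without strand, exons or sequence. The 21887 protein-coding genes on the 21 main chromosomes were used, and 3 regions outside these chromosomes were left out of gene analyses. A region was given to the protein-coding gene whose body lay nearest to its centre, at most 100 kb away, and to each gene where bodies overlapped. The planned distance to a transcription start was replaced by distance to the nearest end of any coding gene body, called a gene boundary, since strand was not in the table. Near a boundary means within 1 kb. The share of the genome inside gene bodies or near boundaries was taken from the span between the outermost coding genes of each chromosome.

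The tests of FOS regions by location, score and gene list, the rule for naming genes and the gene lists were fixed before the data were examined. All tests that use the IL-33 list or the number of calls, those of shared regions included, were chosen after seeing the data. The lists covered AP-1, immediate early genes, pattern recognition, IL-33 and MYD88 signalling, NF-kappaB, MAP kinases, cytokines, microglia, phagocytosis, complement, interferon and markers of other cells. There were 20 lists, and 467 of 470 entries matched a gene. Of 454 different genes, 13 stood on 2 or more lists, among them Itgam, Itgax, Mertk, Trem2, Cd36, Stab1 and C1qb. Genes with at least 1 region were compared with all other coding genes by a two-sided Fisher's exact test per list, with Benjamini-Hochberg adjustment over the 20 lists at 0.05. Median scores were compared by a two-sided permutation test with 100000 permutations. Shares have exact Clopper-Pearson 95% intervals. Overlap of IL-33 list peaks with FOS peaks was compared with 1000 random placements on the same chromosome and with fixed shifts, with 320 bp taken as the width of a FOS peak and 500 bp as that of an IL-33 list peak. On simulated data of the same size, with 90.0% of the members of planted lists given a FOS region, Fisher's test recovered 96.0% of the lists. It recovered 87.0% with 30.0% of members given a shared region, and false calls stood at 1.6% and 0.413% of unplanted lists.

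The rule for naming genes takes the genes of the 15 highest deposited scores, the 3 members with the highest-scoring region in each list, and 17 genes chosen for the question, from Fos and Jun to Tmem119 and Sall1. With the restored score 14 of the 15 and 57 of the 60 were the same. The result of 1 gene that the rule names is not reported here. Alternatives were a score filter, merging of close peaks, other distances, matched random lists, other gene backgrounds and filters on calls. The AP-1 motif test was not run, since no genome sequence was used here. The fit of FOS over input and the agreement between mice were not run either, since no values per library were analysed here. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.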

Results

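FOS, a subunit of the AP-1 transcription factor that neurons and immune cells induce within minutes to hours of stimulation, was mapped in cortical microglia of 4 mice 4 h after an injection of IL-33, a cytokine of the interleukin-1 family. The deposited table held 32773 regions on mm10. Of these, 31473 carried a FOS peak and 2848 carried a peak of the IL-33 list. There were 29925 FOS-only regions, 1548 shared regions and 1300 IL-33-only regions. The median width was 320 bp for FOS-only and 500 bp for shared regions.

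The 15 genes with the highest deposited scores ranged from Ergic1 at 142 to Socs3 at 117. The top region lay on chromosome 17 at 26535259 to 26535650, 25308 bp outside the nearest coding gene Ergic1. A region scoring 99.8 at 26533841 to 26534185 was assigned to Dusp1 and lay 25541 bp outside it. Dusp1 encodes a phosphatase that inactivates MAP kinases. Regions within the 15 highest deposited scores were also assigned to Cebpb (135, chromosome 2, 167753927 to 167754275) and Il1a (129, chromosome 2, 129319970 to 129320391). They lay 63669 bp outside Cebpb, a transcription factor of inflammatory myeloid cells, and 9994 bp outside Il1a, an interleukin-1 family cytokine. Others lay 13635 bp outside Itgam (128), which encodes the CD11b chain of complement receptor 3, and inside Cx3cr1 (126, chromosome 9, 120058754 to 120059085), the fractalkine receptor of microglia. For the remaining genes of the 15, the region lay inside Serinc3 (135), Fyb (131), Cpd (122), Ccl4 (121), Cdk6 (117) and Rcan1 (117). It lay outside Wfdc21 (122, 9512 bp), C3ar1 (122, 6981 bp), Cd69 (118, 34374 bp) and Socs3 (117, 19375 bp). All 15 regions were merged from 4 calls. The highest score in a shared region lay inside Vmp1 on chromosome 11, at 131 after restoration and 65.3 as deposited, so that Vmp1 replaced Socs3 among the 15 when the restored score was used.

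FOS regions differed in the number of calls merged into them. Of these regions, 12511 rested on 1 call, 6393 on 2, 5355 on 3 and 7214 on 4, and the median score rose with the number of calls from 12.4 through 19.4 and 24.7 to 35.7. FOS-only regions with a single call had 4 widths, and 6362 of 12305 (51.7%) had a width of 270 bp. Their median score was 12.4 at 270 bp, 6.5 at 274 bp, 11.6 at 302 bp and 15.6 at 320 bp. Whether each width stands for a single library, and whether scores are comparable between widths, is not given in the sources used here. Among the 17 genes chosen beforehand, Tnfaip3, which encodes the NF-kappaB inhibitor A20, had 10 of its 16 FOS regions from 4 calls, Atf3 6 of 7, Ccl2 6 of 8, Fos 6 of 15, Tlr2 4 of 5 and Cd14 3 of 3, all counted within 100 kb. Within 10 kb the number of FOS regions was 2 for Tnfaip3, Atf3, Ccl2 and Tlr2 each, and 3 for Fos and Cd14. Junb had 1 region and Tmem119 had 3, none of them from 4 calls.

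Which genes carried FOS regions was asked with lists fixed beforehand. Of 21887 coding genes, 11076 (50.6%) had at least 1 FOS region. The list tests, here and below, did not match genes by expression or open chromatin in microglia. They therefore cannot tell a preference of FOS for a list from a list of genes active in microglia. All 21 members of the NF-kappaB list and all 21 of the MAP kinase list had one (adjusted p = 3.9e-06 for each, Fisher's exact test). Among NF-kappaB genes the highest scores stood at Nfkbia (106), Tnfaip3 (102) and Nfkb1 (74.2, in a shared region), followed by Rel (66.3). The highest deposited score over all regions of Nfkb1 was 39.7. Among MAP kinase genes the highest scores stood at Mapkapk2 (89.5), Map3k14 (66.8) and Mapk3 (62.8). The homeostatic microglia list had 30 of 31 members with a FOS region (adjusted exact p = 3.8e-07), with P2ry12 at 71.5, and P2ry13 as the member without. Pattern recognition receptors had 36 of 39 (adjusted exact p = 3.8e-07), led by Nod2 (86.1), Cd14 (77.3) and Nlrp3 (70.4), with Tlr4 at 57.6 and Tlr2 at 55.9. Cytokines and chemokines had 32 of 35 (adjusted exact p = 2.9e-06). AP-1 and related factors had 19 of 20 (adjusted exact p = 0.000102), with Fosl1 as the member without. Their highest scores stood at Fos (85.9), Batf (84.7), Batf3 (75.4) and Nfe2l2 (72.8). The highest deposited score over all regions of Batf was 56.8.

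Other groups with more FOS-bound members than the remaining genes were immediate early genes (27 of 30, adjusted exact p = 2.48e-05, with Dusp1, Btg2 and Ier3 highest) and activated microglia genes (30 of 33, adjusted exact p = 4.84e-06, with Cd9 at 116, Cd52 at 90.3 and Cd44 at 82.5). The IL-33 receptor and MYD88 list had 19 of 21 (adjusted exact p = 0.000498), with Irak2 at 77.5, Myd88 at 34.3 and Il1rl1, the gene of the IL-33 receptor ST2, at 33.6. Phagocytosis genes, not all of which encode receptors, had 25 of 31 (adjusted exact p = 0.00179, with Lrp1 and Fcgr1 highest). Complement genes had 15 of 19 (adjusted exact p = 0.0322, with C1qb at 98.4). The complement call ended when regions were counted only within 10 kb or 1 kb of the gene or when 3 regions per gene were required. Neuron markers had a FOS region in 7 of 30 (23.3%), fewer than other genes (adjusted exact p = 0.00546), a call that ended with 4-call regions only, with genes at any distance or with at least 3 regions per gene.

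Apart from neuron markers, lists of other cells that a sort could carry along did not pass in either direction with all FOS regions. With 4-call regions only, border-associated macrophage markers passed as higher, and with scores at or above the median the mast cell and type 2 innate lymphoid list passed as lower. Counts were 7 of 18 for monocytes and neutrophils (adjusted exact p = 0.372), 6 of 17 for lymphocytes (0.291), 4 of 13 for mast cells and type 2 innate lymphoid cells (0.233), 6 of 16 for astrocytes (0.363), 5 of 17 for oligodendrocytes (0.132) and 9 of 18 for endothelial and mural cells (1). Border-associated macrophage markers had 9 of 13 (adjusted exact p = 0.314) and interferon-stimulated genes 17 of 24 (adjusted exact p = 0.0988). The highest-scoring members were Ccr2 (40.9), Cd4 (31.7), Il7r (18.9), Slc1a3 (40.2), Cnp (54.2), Flt1 (61.0), Stab1 (59.4) and Ifitm3 (58.1).

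**Figure D1:**
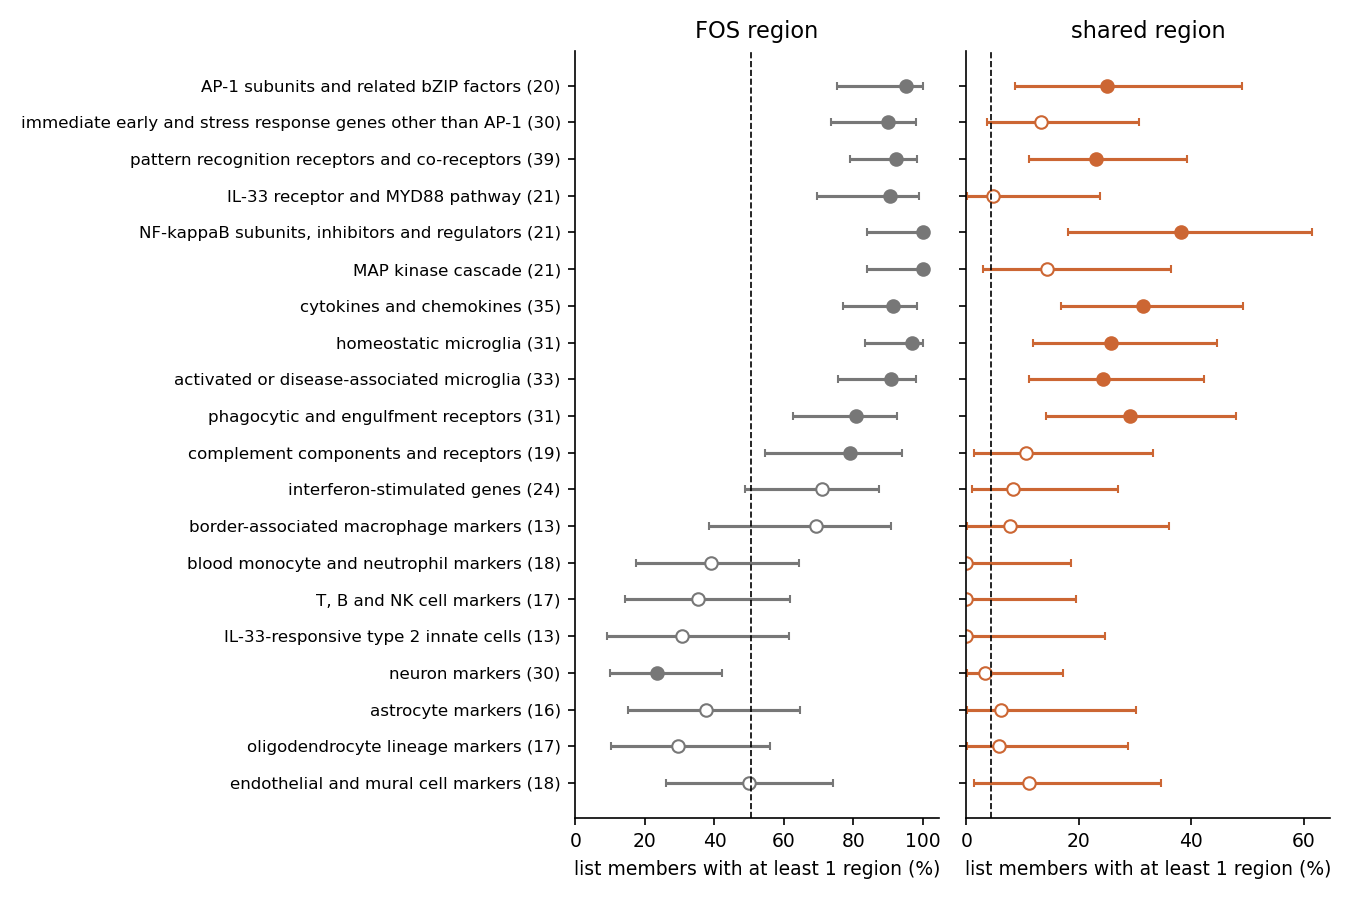
Share of the members of each of the 20 fixed lists with at least 1 FOS region (left) or shared region (right), in percent with exact 95% intervals and the number of members in parentheses; filled points passed the test at an adjusted p of 0.05, and dashed lines give the share over all 21887 coding genes (50.6% and 4.34%). NF-kappaB genes stand at 100% on the left and 38.1% on the right, and neuron markers at 23.3% and 3.33%.

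FOS peaks were frequent in and at the ends of genes. Gene bodies held 58.9% of FOS regions (95% interval 58.3 to 59.4) and 38.4% of the annotated span. A gene boundary lay within 1 kb of 22.0% (21.6 to 22.5), which is 7.49-fold the 2.94% of the span. Boundary regions included the highest-scoring regions of Tnfaip3 (91 bp from the boundary, chromosome 10, 19015303 to 19015700), Cd14 (63 bp, chromosome 18, 36726588 to 36726917), Tlr4 (15 bp, chromosome 4, 66827391 to 66827741), Il1rl1 (95 bp, chromosome 1, 40404591 to 40404948), Nlrp3 (89 bp) and C1qb (93 bp). Highest-scoring regions far from their gene included those of Fos (55468 bp away), Jun (53914 bp) and Atf3 (14770 bp). A further 18.2% of FOS regions lay outside but within 10 kb of a gene body, 17.2% between 10 and 100 kb and 5.67% farther. Strand was not in the annotation used, so a boundary can be either end of a gene.

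Scores were higher near gene boundaries. The median was 24.1 in 6929 regions near a boundary and 18.7 in 24542 regions farther away, a difference of 5.4 (p = 1e-05, permutation test, the smallest value it can give). On the log2 scale the means differed by 0.35. The number of calls went the other way. Near a boundary lay 16.6% of FOS regions of 4 calls, against 22.0% of all FOS regions. Examples near a boundary were Ccl4 (121) and Nfkbia (106, 724 bp), and an example farther away was Cx3cr1 (126, 9377 bp inside the gene). The region of Ccl4 lay inside that gene, and the boundary 142 bp away was not an end of Ccl4.

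The file set the FOS peaks against the IL-33 list, which asks how far regions of that list coincide with FOS binding. Of the 2848 IL-33 list regions, 1548 carried a FOS peak (54.4%, 95% interval 52.5 to 56.2), including regions at Tlr2, Ccl2, Nfkbia, Tnfaip3 and Il1b. Counted by single peaks, 53.4% of IL-33 list peaks overlapped a FOS peak at their own place, against a mean of 1.06% and a highest value of 1.71% in 1000 random placements. After a shift by 2 kb the share was 8.06% on the lower and 7.72% on the higher coordinate side, and after 100 kb 2.36% and 3.04%. Neither the random placements nor the shifts were limited to open chromatin in microglia. They therefore cannot tell a coincidence with FOS in particular from an overlap of 2 lists of active regions. In 1271 shared regions with 1 peak of each list the centres were a median of 34 bp apart, and 85.1% were within 100 bp. In the other direction, 4.92% of FOS regions (4.68 to 5.16) were in the IL-33 list.

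IL-33 list peaks without a FOS peak lay close to FOS peaks as well. The median distance between centres was 1065 bp, and 47.7% of 1371 peaks were within 1 kb. After shifts of 10 to 50 kb it was 5.70% to 10.7%. Shifted peaks that then overlapped a FOS peak were left out, so 1267 to 1317 peaks remained per shift. Inside Cx3cr1, 7 IL-33-only regions lay between 120052731 and 120059863 beside FOS-only regions scoring 98.2 and 126. Cd14 had 3 IL-33-only regions beside 3 FOS-only regions. IL-33 list regions with a peak of 2 or more calls carried a FOS peak in 66.6% (1127 of 1693), and those of 1 call in 36.5% (421 of 1155, p = 4.96e-57, Fisher's exact test). Calls here are the number that ends the name of an IL-33 list peak, and its meaning is not given in the sources used here. A region with several such peaks took the largest number. This can favour shared regions, which held 1855 such peaks in 1548 regions, against 1371 in 1300 IL-33-only regions.

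**Figure D2:**
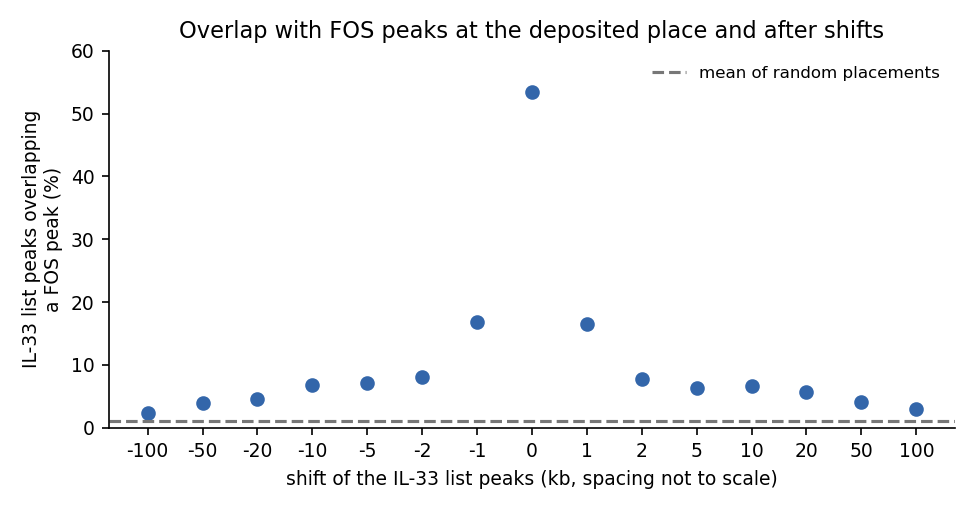
Share of 3226 IL-33 list peaks that overlapped a FOS peak (vertical axis, percent) at their own place and after shifts along the chromosome (horizontal axis, kb), with the mean of 1000 random placements as a dashed line. The share is 53.4% at no shift, 16.8% and 16.6% at 1 kb, and below 9% from 2 kb on.

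**Figure D3:**
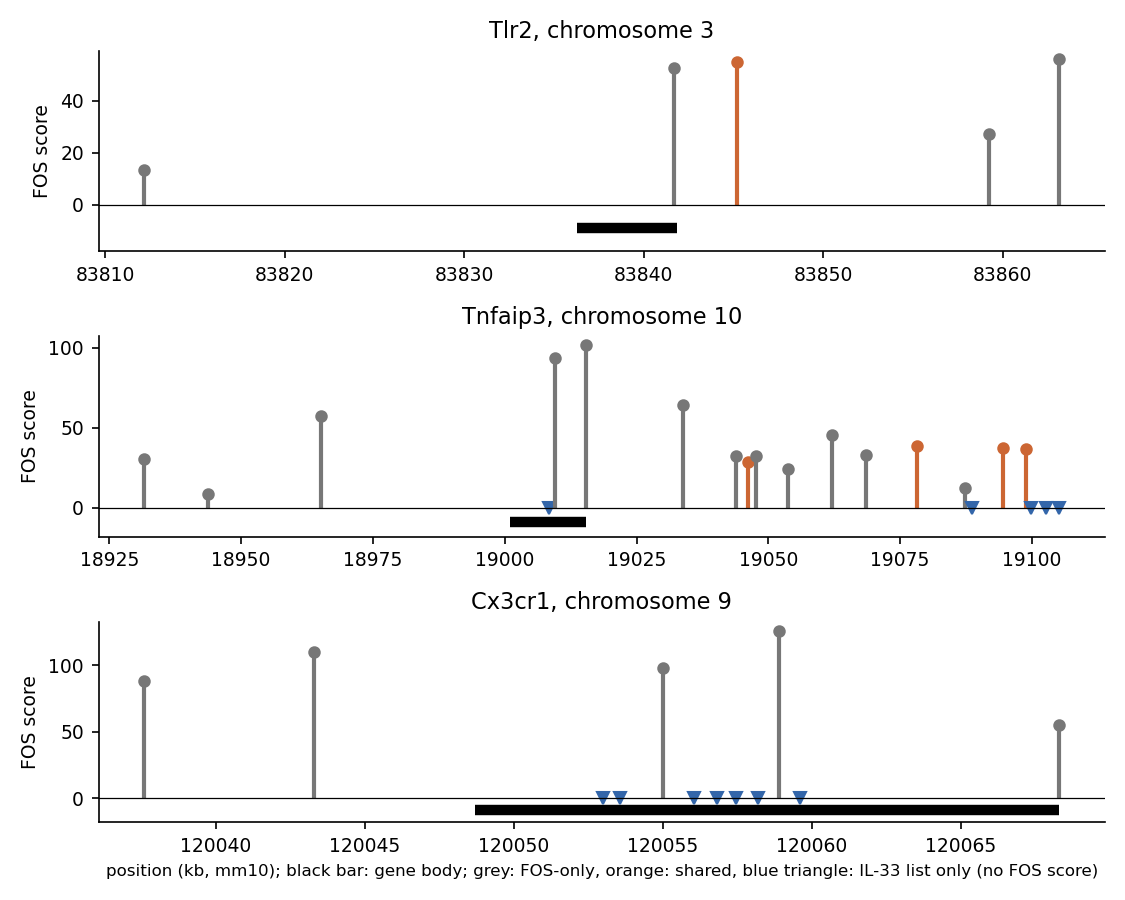
FOS regions and IL-33 list regions assigned to Tlr2, Tnfaip3 and Cx3cr1, by position in kb on mm10 (horizontal axis) and FOS score (vertical axis); grey marks FOS-only, orange shared and blue triangles IL-33-only regions, which have no FOS score, and the black bar is the gene body. Tlr2 has 1 shared region among 5 FOS regions, Tnfaip3 has 4 among 16 and Cx3cr1 has 0 among 5.

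Shared regions were the more recurrent and higher-scoring FOS regions. Of the shared regions, 53.7% (51.2 to 56.3) came from 4 calls, against 21.3% (20.9 to 21.8) of FOS-only regions (odds ratio 4.29, p = 6.69e-161, Fisher's exact test). The share in the IL-33 list was 1.65% at 1 call, 3.08% at 2, 5.85% at 3 and 11.5% at 4. The median score was 30.1 in shared and 19.8 in FOS-only regions, a difference of 10.3 (p = 1e-05, permutation test, the smallest value it can give). Among 4-call regions the medians were 39.1 and 35.2 (difference 3.84, permutation p = 1e-05). Shared regions of 4 calls included those at Vmp1 (131), Il1a (76.0), Itgam (67.8), Nfe2l2 (66.5), Ccl4 (57.1), Socs3 (56.8) and Tlr2 (55.0). With the score as deposited, which averages in the zeros of the IL-33 list, the difference was -5.73.

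**Figure D4:**
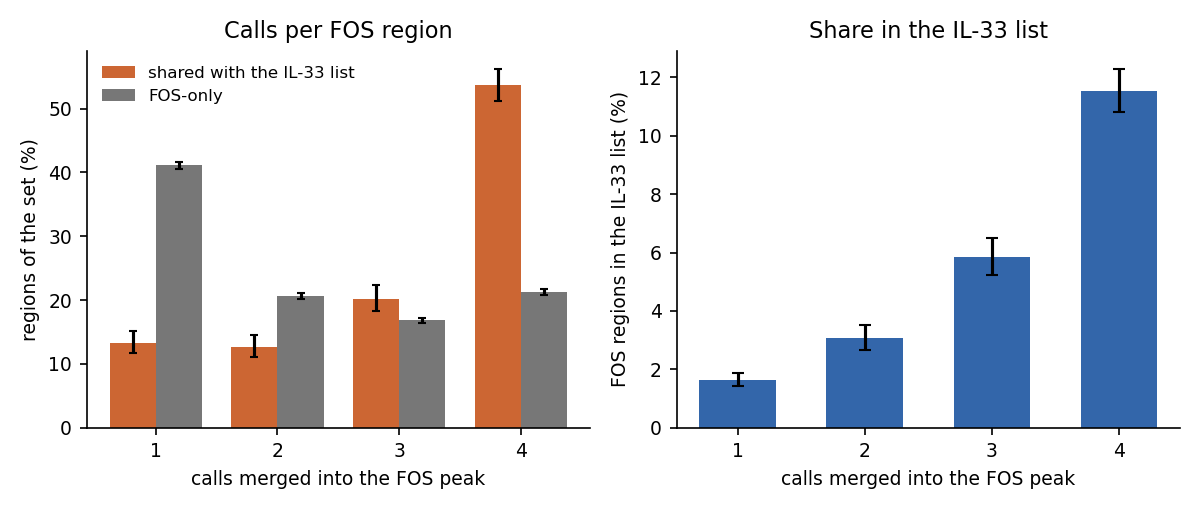
Left, percent of 1548 shared and 29925 FOS-only regions (vertical axis) by the number of calls merged into the FOS peak (horizontal axis); right, percent of FOS regions in the IL-33 list by the same number, both with exact 95% intervals. The share in the IL-33 list is 1.65% at 1 call and 11.5% at 4.

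The 2 lists differed in how often they lay near gene boundaries. Near a gene boundary lay 3.16% of IL-33 list regions (2.55 to 3.87), against 23.0% of FOS-only regions (odds ratio 0.109, adjusted exact p = 1.36e-185, Fisher's exact test) and 2.94% of the span. Shared regions stood at 2.78% and IL-33-only regions at 3.62%. In the upper quartile of FOS scores, 13.3% of regions away from boundaries were in the IL-33 list and 1.04% of those near them. The boundary regions of Tnfaip3, Nfkbia, Cd14, Tlr4, Nlrp3 and C1qb that led their genes by score were FOS-only. So were the leading regions of Cebpb, Fos, Fyb and Itgam away from boundaries, so these examples are not particular to boundaries. Inside gene bodies lay 53.4% of shared and 59.1% of FOS-only regions (odds ratio 0.792, adjusted exact p = 1.59e-05), but IL-33-only regions did not pass that test against FOS-only regions (780 of 1299, adjusted exact p = 0.526). The whole IL-33 list stood at 56.4%, against 55.5% of FOS-only regions of 4 calls (adjusted exact p = 0.417).

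Shared regions were assigned to 950 genes (4.34%). NF-kappaB genes had the largest share of the 20 lists, with 8 of 21 members (38.1%, adjusted exact p = 1.5e-05, Fisher's exact test): Nfkb1, Nfkbia, Nfkbiz, Bcl3, Tnfaip3, Tnip1, Birc3 and Traf1, several of which encode inhibitors of the pathway. Cytokines and chemokines had 11 of 35 (adjusted exact p = 3.11e-06), namely Il1a, Il1b, Il12b, Osm, Csf2, Ccl2, Ccl4, Ccl5, Ccl12, Cxcl2 and Cxcl13. Like the other list tests, this one counts genes as independent. Some of these genes lie close together on a chromosome, such as Il1a with Il1b and Ccl4 with Ccl5. Phagocytosis genes had 9 of 31 (adjusted exact p = 2.98e-05): Itgav, Itgb5, Fcgr3, Havcr2, Elmo1, Dock2, Mertk, Trem2 and Cd36. Of these, Mertk, Trem2, Cd36 and Itgav recognise apoptotic cells, lipids or bridging proteins, while Elmo1 and Dock2 do not encode receptors. Pattern recognition receptors also had 9, of 39 (adjusted exact p = 0.000158): Tlr1, Tlr2, Nod1, Aim2, Marco, Cd36, Olr1, Fpr2 and Stab1. Homeostatic microglia genes had 8 of 31 (adjusted exact p = 0.000158), with Itgam, Mertk, Irf8, Mef2c and Tgfbr1 among them, and activated microglia genes 8 of 33 (adjusted exact p = 0.000215), with Ch25h, Itgax, Cd83 and Lpl. AP-1 and related factors had 5 of 20, Fos, Batf, Maff, Bach2 and Nfe2l2 (adjusted exact p = 0.00391). Against genes with a FOS region instead of all genes the AP-1 call ended (adjusted exact p = 0.0552) and the other 6 held. With regions counted only within 10 kb of the gene the AP-1 call ended, within 1 kb the AP-1, cytokine and activated microglia calls ended, and with at least 3 regions per gene the NF-kappaB and cytokine calls were the ones of the 7 that held.

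The remaining lists did not pass the test among shared regions. The IL-33 receptor and MYD88 list had 1 of 21, Map3k8 (adjusted exact p = 0.758), immediate early genes 4 of 30 (0.0986), MAP kinases 3 of 21 (0.135), complement 2 of 19 (0.361) and interferon-stimulated genes 2 of 24 (0.466). Immediate early genes passed as higher with genes at any distance or with scores at or above the median, and MAP kinases with at least 3 regions per gene. Counts were 1 of 13 for border-associated macrophages (adjusted exact p = 0.675), 1 of 30 for neurons (1), 1 of 16 for astrocytes (0.706), 1 of 17 for oligodendrocytes (0.706) and 2 of 18 for endothelial and mural cells (0.361). Monocyte and neutrophil, lymphocyte, and mast cell and type 2 innate lymphoid lists had 0 of 18, 0 of 17 and 0 of 13 members (adjusted exact p = 1 each), which the intervals allow to be up to 18.5%, 19.5% and 24.7%. For the whole IL-33 list, shared or not, 1234 genes (5.64%) had a region and 8 lists passed. These were the 7 above and immediate early genes (8 of 30, adjusted exact p = 0.000479), and homeostatic microglia genes had 14 of 31 (adjusted exact p = 6.55e-09), with Cx3cr1, Csf1r, Spi1 and Bin1 among the members that had no shared region. Within 1 kb of the gene the immediate early and activated microglia calls ended, which left 6 lists, and with at least 3 regions per gene the pattern recognition and phagocytosis calls ended as well, which left 4.

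At single loci, Tlr2, the receptor of bacterial lipoproteins, had a shared region on chromosome 3 at 83844740 to 83845647, 3369 bp outside the gene, with a FOS score of 55.0 from 4 calls. Ccl2, a monocyte-attracting chemokine, had 3 shared regions among 8 FOS regions, the highest at 82006678 to 82007450 on chromosome 11 (56.7, 28513 bp from the gene). Nfkbia had 2 shared regions among 7, 22317 and 22921 bp from the gene, and Tnfaip3 had 4 among 16, from 30818 to 83429 bp away. Il1b had 1 among 9, on chromosome 2 at 129338097 to 129338656 (44.1, 26193 bp away). Fos had 2 among 15, 45904 and 47392 bp away. No shared region was assigned to Tlr4 (4 FOS regions), Cd14 (3), Cx3cr1 (5), P2ry12 (4), Tmem119 (3) or Sall1 (8). The same held for Jun (3), Junb (1), Atf3 (7), Il1rl1 (7) and Myd88 (2). Of these genes, only Cd14 and Cx3cr1 were assigned IL-33-only regions. All counts at these loci are by nearest gene, so regions within 100 kb but nearer to another gene are left out. Counts depended on the distance allowed: within 10 kb there were 3 FOS regions for Nfkbia, 4 for Il1b, 3 for Sall1 and 1 for Jun, and at any distance 21 for Sall1 and 14 for Jun.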

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

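The results on the overlap of the IL-33 list, on shared against FOS-only scores, on the boundary share of the IL-33 list and on gene lists in the IL-33 list and shared regions, with their alternatives, and all filters on calls were chosen after seeing the data. The shares of FOS regions in gene bodies and near boundaries stayed above the span, the score difference by distance to a boundary stayed above 0, and the IL-33 list stayed rarer near boundaries than FOS-only regions, in each alternative run. Lists called for FOS regions numbered 10 to 13 against 12, and those for the IL-33 list within 1 kb 6 against 8. With the deposited score the difference of shared from FOS-only regions was -5.73 in place of 10.3, since that score averages in zeros; at 4 calls it was 3.84. A score at or above the median left 15768 of 31473 FOS regions, by construction. With at least 3 regions per gene, 4 lists in place of 8 passed for the IL-33 list and 3 in place of 7 for shared regions, and within 1 kb 4 passed for shared regions; the cause was not tested. The share of IL-33 list regions with a FOS peak, 54.4%, was 47.1% with FOS peaks of 2 or more calls, 29.2% with 4 calls and 42.8% with scores at or above the median, which leave fewer FOS peaks. It was 66.6% for IL-33 list peaks of 2 or more calls (the cause was not tested), and 51.3% or 76.9% when centres had to lie within 250 bp or 1 kb. Of the calls of single lists as higher, 85 of 88 for FOS, 42 of 48 for the IL-33 list and 53 of 63 for shared regions held over the alternatives. Of the 17 genes chosen for the question, the number of FOS regions moved by over 1.5 times in 9 within 10 kb and in 2 at any distance; the smaller or wider window sets how many regions can be assigned. No paired analysis was possible because the table had no values per library, and for the same reason leave-one-out fits, the FOS over input alternatives and those for agreement between mice were not run. The AP-1 motif alternatives were not run without a genome sequence, nor was the overlap without single-call FOS peaks of 270 bp, since widths inside shared regions are those of the merged region. Depth per library is unknown, so peaks missed in a library cannot be separated from shallow sequencing.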

Other observations

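Of the tests below, the restoration of the score, the expected number on the X chromosome by score and the boundary share of 4-call regions were chosen only after the result was seen. The genes in the next paragraph were picked after their values were seen.

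Genes with many shared regions included long and short ones. Lpp had 15 among 44 FOS regions and Etv6, an ETS family repressor, had 10 among 27, but both are long, at 599229 and 234459 bp. Short genes with many were Ch25h (1366 bp, 7 shared among 9 FOS regions), which encodes the enzyme making 25-hydroxycholesterol, and Cxcl13 (4130 bp, 6 among 9), which encodes a chemokine that attracts B cells. Pik3cg, the gamma catalytic subunit of phosphoinositide 3-kinase, had 8 among 14, Rbpj, the DNA-binding partner of Notch, 7 among 11, Zeb2 7 among 15 and the chemokine receptor gene Ccr7 5 among 9. Over the whole IL-33 list, Etv6 and the Src family kinase gene Lyn had 25 regions each, Zeb2 22 and Lpp 19. Nfkbiz had 10 IL-33 list regions, of which 4 were shared.

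The higher score of shared against FOS-only regions appears only after the averaging is undone. Averaging with zeros accounts for the lower deposited score, as 98.7% of the 1517 shared regions checked gave whole multiples of 0.1 after multiplication. A stronger signal of the whole neighbourhood is argued against as the full cause, since shared regions exceeded the nearest FOS-only region within 50 kb by a median of 0.19 on the log2 scale (interval 0.14 to 0.25) and in 58.7% of 1507 pairs (p = 1.32e-11, exact sign test). Longer merged regions are also argued against, because with 1 peak of each list the difference of medians was 10.35. Shared regions close together can have the same nearest FOS-only region, and the sign test and interval count their pairs as independent. The step to the nearest neighbour is smaller than that between the medians of all shared and FOS-only regions, 30.1 and 19.8, so part of the gap may lie in the neighbourhood, and no biological explanation was tested.

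The IL-33 list was rare on the X chromosome, with 22 regions (2.56 per 100 FOS regions) against 6.52 to 12.7 per 100 on the autosomes. Fewer clusters on X argue against a few large autosomal clusters as the cause, with 0.0865 IL-33 list clusters per FOS cluster on X and 0.167 to 0.432 on the autosomes. Weaker FOS peaks on X were tested by autosomal rates per number of calls and boundary, which gave 40.3 shared regions against 14 observed (Poisson 95% interval 7.65 to 23.5), but calls do not carry the difference, since 4-call regions on X had a median score of 17.8 against 36.0 on the autosomes. Rates per score decile and boundary gave 16.9, within that interval. IL-33-only regions have no FOS score and were left out of these rates, so their number on X was not tested. For the shared regions alone, lower scores on X could account for the shortage. A single X copy in male mice may be behind such scores, but the sex of the mice is not given in the sources used here and this was not tested.

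IL-33 list regions were rarer near gene boundaries than FOS-only regions, but not than the span of the genome, at 3.16% against 2.94% (p = 0.471, exact binomial test). Single-call FOS peaks at boundaries are argued against as the cause, since 18.4% of FOS-only regions of 4 calls lay there. Whether the authors had left out promoter regions from the IL-33 list stays open, since few regions are expected where the test could be made. In places within 1 kb of both ends of a coding gene there were 0 IL-33 list regions with 2.51 expected from the span, inside the Poisson limit of 3.69, while FOS-only regions numbered 63 there with 26.4 expected. No biological explanation was tested.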
